A study of Mus musculus with 43 samples.

How the data were processed

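Gene expression was measured on 43 2-colour Agilent whole-genome mouse arrays (44K format), each hybridised with a Cy5-labelled sample of mouse embryonic fibroblasts (MEFs) and a Cy3-labelled sample of untreated cells of the same line. There were 3 lines: wild type (WT) and 2 knockout lines, KO1 and KO3, derived from embryos with a knockout of the heme oxygenase 1 gene Hmox1. Cy5 samples had received 10 µM heme for 1, 4 or 8 h. On the control arrays (0 h) both channels held untreated cells. All arrays had the same dye orientation, so a dye effect that a gene shows in every array cancels against the control arrays and any other dye effect stays in the ratio. The groups held 4 arrays each, except KO3 with 2 control arrays and 3 treated arrays at each time. The arrays came from 13 slides read on 5 scan days. No record says that replicate letters pair the samples. Of 30 pairs of a treated and a control array of a line with the same letter, 15 had a correlation of residuals over 0.1 (range -0.13 to 0.29). The control array with the same letter was the most alike in 15 of the 15 pairs on the same slide and in 5 of the 15 on different slides, so the likeness largely follows the slide. Letter and slide were used in alternatives only.

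Per the file headers, the authors extracted the images with Agilent Feature Extraction 10.7.3.1, and each deposited scanner file gives median spot and local background signals as intensity (not background-subtracted or dye-normalised) and processed signals as intensity after background subtraction, spatial detrending and dye normalization. The deposited series value table holds log10 ratios of the processed Cy5 over Cy3 signals, with 2.9% to 38.9% of the values of an array exactly 0. Each of its columns was checked against the scanner file of that array and was equal to it at every spot, so the value table carries no centring between arrays. The scanner files have no mean signal column, so median signals took the place of the mean signals that the design named.

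Analysis used R 4.3.3 with limma 3.58.1, statmod 1.5.0 and the package data.table (version 1.17.8). Median signals were background-corrected with limma's normexp method (offset 50), turned into log2 ratios of Cy5 over Cy3 and normalised by loess within each array, with no scaling between arrays. Spots marked as population or non-uniformity outliers were set to missing (2214 gene values), and repeated spots of a probe were averaged. Of 39429 probes that are not controls, 27612 were well above background in at least 1 channel on at least 2 arrays of a group and were kept. Probes were given symbols through their RefSeq accession (25868 of 26391 accessions starting NM matched), which left 20306 kept probes with a symbol. For each of 15615 genes the kept probe with the highest mean intensity was used. Genome positions of the probes were not analysed here.

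A single limma model with a mean for each group was fitted to all 43 arrays. For each line, 1, 4 and 8 h of heme were compared with the control arrays. The mean of the changes of both knockout lines minus the change in WT (KO minus WT) and the change in KO1 minus the change in KO3 were tested as contrasts of the same model, two-sided, with Benjamini-Hochberg adjustment over the genes of each contrast and a threshold of adjusted p 0.05. These contrasts compare changes from each line's own control arrays, so the untreated level of a line does not enter them directly. With 1 WT line and 2 knockout lines, an effect of the genotype cannot be told apart from other differences between the lines. Errors of log2 changes are standard errors (SE) from the model. The model uses 1 estimate of spread per gene for all groups, so an SE does not measure the spread within the groups compared. Errors of array values are standard deviations (SD) between arrays.

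Gene lists were 17 pathway lists (targets of NRF2 and BACH1, iron and heme, cytosolic heat shock, proteasome subunits, unfolded protein response of the endoplasmic reticulum, ATF4 and the integrated stress response, metallothioneins, immediate early genes, p53 targets, cell cycle, cholesterol synthesis, NF-kappaB, interferon, collagens and matrix, TGF-beta with YAP and SRF, glycolysis and hypoxia, autophagy and lysosome) and 6 marker lists of other cell types (leukocytes, epithelium, endothelium, muscle, neural and erythroid cells), all written from general knowledge. Lists were tested with limma's cameraPR (preset correlation 0.01) with adjustment over 345 tests of 23 lists in 15 contrasts. Of these, 125 passed, and 28 passed with a correlation estimated from the residuals (camera), all among the 125. Limma's fry was also run. The lists share few genes: 3 are in both the NRF2 and the iron list, and 5 other pairs of lists share 1 gene each.

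The groups, tests, lists, most alternatives and the rule for the genes named were fixed before the data were examined. The rule takes Hmox1 in every contrast. For each line and time it takes the 5 largest rises and 5 largest falls (10 each at 8 h) among genes past the threshold whose ratio lay on the same side of the control mean in every treated array. For KO minus WT it takes the same numbers among genes past the threshold with the same sign in both knockout lines. For each list and contrast it takes up to 4 members with the smallest adjusted p. Features without a symbol and names of unnamed transcripts were passed over. 1 gene that the rule takes is not reported here, though counts include it.

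Alternatives changed 1 choice at a time: Agilent processed signals, no background subtraction, median centring in place of loess, scale normalization between arrays, no filter or a stricter filter, the mean of a gene's probes, a fit of a single line, an intensity trend with a robust prior, array quality weights, no control arrays, the replicate letter, slide or scan day as a block, the series value table, and each array left out in turn. After the data were seen, 3 alternatives were added: 5 arrays that stood apart left out, the slide 9 control arrays left out, and extreme local backgrounds replaced. The last was added because on 6 arrays between 21 and 77 spots with very high local background widened the fitted normexp background (Cy5 SD of 246 to 1696, against at most 154 on the other 37), which flattened the ratios of those arrays. Replacing local backgrounds over 2 times the array median by that median brought the SD to at most 4.63. The corrected counts are given beside the planned ones where they differ by more than 1.5 times.

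Median spot signals were 83 to 543 in Cy3 (median 120) and 124 to 1306 in Cy5 (median 166), against negative control spots of 42 to 94 and 58 to 115. Between 19455 and 39622 spots per array were well above background in Cy3 and between 22600 and 40543 in Cy5, and no spot was saturated. The number of arrays limits the precision. The model was tested on simulated data with 50 changed genes per size, drawn with 1 residual spread per gene for all arrays. At 8 h a change of 1 on the log2 scale was called for 92% of genes in WT, 96% in KO1, 84% in KO3 and 88% in KO minus WT. A change of 0.5 was called for 38% to 64%. The real arrays differed in spread (array quality weights from 0.15 on KO1_8h replicate a to 6.12 on WT_0h replicate a), so these shares may not hold for them. In a simulation where 1 of 23 lists was shifted by 0.5, the list test called 1. Genes were simulated as independent of each other, so this cannot show false calls that arise from correlated members of a list. The simulated data also held far fewer changed genes than were called in the knockout lines at 8 h. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.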

Results

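Transcript levels were compared between MEFs treated with 10 µM heme for 1, 4 or 8 h and untreated cells of the same line, in a WT line and in 2 lines from Hmox1 knockout embryos (KO1 and KO3). WT and KO1 had 4 arrays per time and 4 control arrays, and KO3 had 3 arrays per time and 2 control arrays. Each array gave log2 ratios of treated over untreated cells for 15615 genes. Median spot signals were 83 to 543 in the untreated channel and 124 to 1306 in the other channel. The SD of the log2 ratios of all genes within an array was between 0.13 and 0.93, and the correlation between a pair of arrays across genes (13663 genes without a missing value, which are not independent replicates) was between -0.12 and 0.97. The comparisons ask which genes heme changes in each line. They also ask whether the 2 knockout lines of heme oxygenase 1, the enzyme that degrades heme, respond differently from the WT line.

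Hmox1 encodes heme oxygenase 1, and its transcription is released when heme displaces the repressor BACH1. With probe A_51_P263965, Hmox1 rose in WT by 1.48 ± 0.24 on the log2 scale (SE, 4 treated and 4 control arrays, adjusted p = 0.0054) at 1 h, by 4.06 ± 0.24 (adjusted p = 4.9e-14) at 4 h and by 3.25 ± 0.24 (adjusted p = 3.6e-11) at 8 h. The same probe rose in KO1 by 2.13 (adjusted p = 5.2e-06), 5.24 (adjusted p = 1.7e-17) and 5.71 (adjusted p = 1.6e-19). In KO3 it rose by 1.80 ± 0.32 (adjusted p = 0.0315), 4.44 ± 0.32 (adjusted p = 6.9e-12) and 4.99 ± 0.35 (adjusted p = 8.1e-13), the last from the 2 of 3 arrays with a usable spot. The ratio was above the control mean in every treated array with a value. The rise was larger in the knockout lines than in WT at 8 h (difference 2.10 ± 0.32, adjusted p = 4.3e-06). The difference did not pass at 1 h (0.48, adjusted p = 1.00) or at 4 h (0.78 ± 0.32, adjusted p = 0.239), where KO1 alone differed from WT (adjusted p = 0.0363, against 0.954 in KO3), and KO1 and KO3 did not differ at 8 h by this test (0.72, adjusted p = 0.303). A second Hmox1 probe, A_55_P2029687, had a mean log2 signal in untreated cells of 10.50 (SD 0.48, 16 arrays) in WT, 7.62 (SD 0.13, 16 arrays) in KO1 and 7.65 (SD 0.11, 11 arrays) in KO3. The log2 change of this probe with heme was 1.30, 3.51 and 2.88 in WT and lay between -0.08 and -0.32 in the knockout lines, and it was not the probe used in the fit. With the first probe, untreated signals were 14.39 in WT, 13.65 in KO1 and 13.41 in KO3. Which part of the gene each probe lies in was not analysed here, so the rise in the knockout lines is one of transcript at that probe and does not speak for the enzyme.

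**Figure D1:**
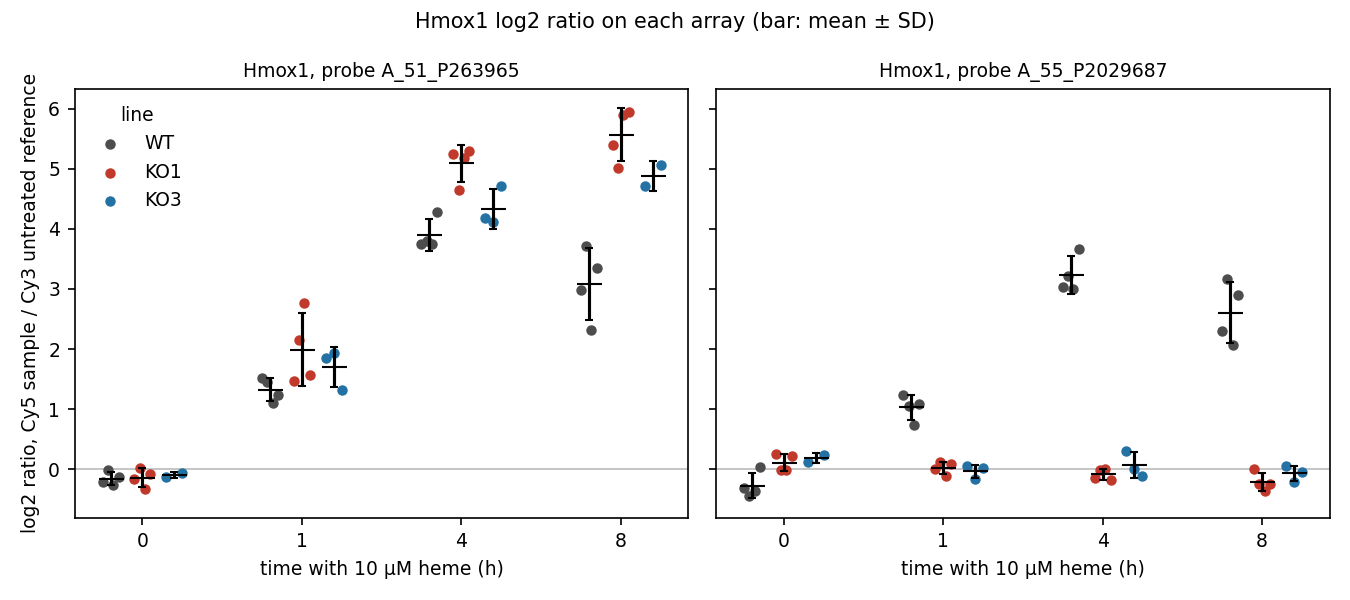
Log2 ratio of Hmox1 (heme-treated over untreated cells) on each array by line and hours of heme, for each of the 2 probes, with points for arrays and bars for the mean ± SD. Probe A_51_P263965 rose in all 3 lines (at 4 h by 4.06 in WT, 5.24 in KO1 and 4.44 in KO3), while A_55_P2029687 stayed near 0 in KO1 and KO3.

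Alas1 encodes the first enzyme of heme synthesis and is repressed by heme. In WT at 1 h it fell by 1.28 ± 0.17 on the log2 scale (adjusted p = 1.2e-04, probe A_55_P2083649). As the rule for the genes named requires, it lay below the control mean in 4 of 4 arrays. Its second probe gave -0.24. Rmnd1, needed for mitochondrial translation, fell by 0.46 ± 0.09 (adjusted p = 0.0357), and with Hmox1 these were the 3 genes that passed in WT at 1 h (814 at unadjusted p under 0.05). In KO1 at 1 h, Hmox1 and Alas1 passed, and Alas1 fell by 1.02 ± 0.17 (other probe -0.05, adjusted p = 0.0058, 689 genes at unadjusted p under 0.05). In KO3 at 1 h Hmox1 alone passed (138 at unadjusted p under 0.05). No gene passed for KO minus WT or for KO1 minus KO3 at 1 h with limma (270 and 152 genes at unadjusted p under 0.05). At 1 h the immediate early genes, which code for transcription factors induced within minutes, had no member past the threshold in WT, yet the list shifted as a whole (median 0.28, adjusted p = 0.0034), which was lost at adjusted p = 0.639 with an estimated correlation. Of the named calls at 1 h, Rmnd1 and Hmox1 in KO3 were the least stable, lost in 17 of 27 and 13 of 24 refits (alternatives and arrays left out).

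At 4 h in WT the largest rise after Hmox1 was that of Ccl2, a chemokine that attracts monocytes, by 3.88 ± 0.22 (adjusted p = 9.6e-15, probe A_51_P286737). Cxcl5, a chemokine that attracts neutrophils, rose by 3.15 ± 0.55 (adjusted p = 7.0e-04). The glutathione transferases Gsta2 and Gsta1 rose by 3.55 ± 0.48 and 3.45 ± 0.36. Alas1 fell by 1.82 ± 0.17 (adjusted p = 4.6e-09, other probe -0.40), the transcription inhibitor Id3 fell by 1.52, the cholesterol exporter Abca1 fell by 0.89, the BMP signal inhibitor Smad6 fell by 0.87 (adjusted p = 0.0476) and the transcription factor Klf5 fell by 0.79. Each of these lay on the same side of the control mean in 4 of 4 treated arrays, as the rule for the genes named requires. The Smad6 call was lost in 14 of 27 refits. In all, 250 genes passed (233 up and 17 down), 68 of them by at least 2-fold, and 1497 had an unadjusted p under 0.05.

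Of the 33 NRF2 and BACH1 targets, which code for antioxidant and iron storage proteins, 19 rose in WT at 4 h, none fell and 14 did not pass (25 up adjusted over the list alone). The list median was 0.77 (adjusted p = 4.3e-37). The thioredoxin reductase Txnrd1 rose by 1.74 ± 0.24 and Gclc, the rate-limiting enzyme of glutathione synthesis, by 1.89 ± 0.29. Cholesterol synthesis genes also rose, 17 of 25 (22 adjusted over the list alone, median 0.79, adjusted p = 3.5e-31), among them the enzymes Lss (1.23 ± 0.20), Sqle (1.24) and Fdps (1.07). Of 28 NF-kappaB and inflammatory genes, 14 rose (15 adjusted over the list alone, median 0.69, adjusted p = 4.9e-24). Among them were the growth factor Csf1 (2.11), the chemokine Ccl7 (2.62) and the adhesion molecule Vcam1 (2.55). Of 35 ATF4 targets, which respond to amino acid shortage and translational stress, 6 rose (20 adjusted over the list alone, median 0.43, adjusted p = 1.4e-15). Of 27 p53 targets, 7 rose (16 adjusted over the list alone, median 0.47, adjusted p = 6.1e-15). They included the death receptor Fas (1.47) and the p53 ligase Mdm2 (0.80). These 5 lists kept their call with an estimated correlation, at adjusted p = 0.0037, 0.0150, 7.8e-04, 0.0467 and 0.0023. The metal-binding metallothioneins Mt1 (0.66, adjusted p = 0.0266) and Mt2 (0.82, adjusted p = 0.0402) were the 2 members of 7 that rose in their list (2 adjusted over the list alone), whose call (adjusted p = 0.0113) was lost at adjusted p = 0.213 with an estimated correlation.

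At 8 h in WT the largest rises were those of Gsta2 (SE 0.48, adjusted p = 3.6e-07, probe A_55_P2170454), Gsta1 by 3.88, Cxcl5 by 3.64, Ccl2 by 3.60, Gsta3 by 3.59, Hmox1 by 3.25, Gsta4 by 2.23, Vcam1 by 2.16, Ccl7 by 2.12 and the neutrophil chemokine Cxcl1 by 2.08 (adjusted p = 0.0157). Cyp1a1, a monooxygenase under the aryl hydrocarbon receptor, fell by 3.36 ± 0.50 (adjusted p = 4.5e-05, probe A_51_P279693), and the gap junction gene Gjb2 fell by 2.36 ± 0.37 (adjusted p = 8.6e-05). Other falls were those of Flrt1 (-1.90, other probes -0.51 and -1.50), Alas1 (-1.68, other probe -0.43), Nrip3 (-1.64), the myosin light chain Myl9 (-1.46), Cpm (-1.33), the transferrin receptor Tfrc (-1.31, other probe -0.63, adjusted p = 0.0454), Kctd12 (-1.31) and Gpd1 (-1.21). Each held in 4 of 4 treated arrays, as the rule for the genes named requires. The Tfrc call was lost in 14 of 26 refits. In all 615 genes passed (348 up and 267 down), 89 of them by at least 2-fold, and 2627 had an unadjusted p under 0.05.

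NRF2 targets stayed raised in WT at 8 h, with 21 of 33 up and none down (27 up and 1 down adjusted over the list alone, median 0.89, adjusted p = 1.4e-28). Among them were the ferritin heavy chain Fth1 (1.47 ± 0.18) and the malic enzyme Me1 (0.97). This call, that of NF-kappaB genes (8 of 28 up, 13 adjusted over the list alone, median 0.42) and that of p53 targets (4 of 27 up, 9 adjusted over the list alone, median 0.37) held with an estimated correlation, at adjusted p = 0.010, 0.0211 and 0.0212. Iron and heme genes split, with 6 of 34 up and 2 down (10 and 3 adjusted over the list alone). The heme transporter Slc48a1 rose by 1.59 and the ferritin light chain Ftl1 by 1.45. The call of that list (adjusted p = 0.0227) was lost at adjusted p = 0.260 with an estimated correlation. Proteasome subunits rose in 4 of 38 cases (12 adjusted over the list alone, median 0.20, adjusted p = 1.2e-06). Psmd1 rose by 0.51, and the call was lost at adjusted p = 0.586 with an estimated correlation. Of 31 cytosolic heat shock genes, which code for chaperones, 2 rose (5 up and 1 down adjusted over the list alone, median 0.19, adjusted p = 0.0071), lost at adjusted p = 0.680 with an estimated correlation. Interferon response genes rose in 3 of 31 cases (9 adjusted over the list alone, median 0.35, adjusted p = 1.3e-06, 0.511 with an estimated correlation), as they did at 4 h (3 of 31, 3 adjusted over the list alone, median 0.27, adjusted p = 2.6e-05, 0.560 with an estimated correlation). Cell cycle genes fell in 4 of 34 cases (9 adjusted over the list alone, median -0.22, adjusted p = 1.4e-05), lost at adjusted p = 0.586 with an estimated correlation. Leaving out 1 array in turn gave 100 to 214 genes at 4 h and 299 to 734 at 8 h.

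In KO1 at 4 h the largest rise after Hmox1 was that of the HSP40 chaperone Dnajb1, by 4.74 ± 0.34 (adjusted p = 1.3e-12, probe A_51_P153486). The HSP105 chaperone Hsph1 rose by 4.46 ± 0.24, the proteasome-associated Zfand2a by 4.48 ± 0.30 and the peroxiredoxin repair enzyme Srxn1 by 4.68 ± 0.34. Falls were led by Ccn2, a matrix protein and YAP target (fell by 2.84 ± 0.58, adjusted p = 3.5e-04), and the junction protein Ajuba (fell by 2.56 ± 0.31, adjusted p = 1.1e-07). They also took in the water channel Aqp5 (-2.28, other probe -1.36), Ccn1 (-2.27) and Depp1 (-2.23). All held in 4 of 4 treated arrays, as the rule for the genes named requires. In KO1 3585 genes passed at 4 h (2064 up and 1521 down), 473 of them by at least 2-fold. Scale normalization between arrays gave 487, and with median centring fewer passed and a larger share of them rose.

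The heat shock list rose in KO1 at 4 h in 28 of 31 members with none down (31 adjusted over the list alone, median 1.93, adjusted p = 8.5e-47). ATF4 targets rose in 27 of 35 (32 adjusted over the list alone, median 1.25, adjusted p = 2.9e-24), and NRF2 targets in 26 of 33 (28 adjusted over the list alone, median 1.33, adjusted p = 4.9e-24). With an estimated correlation these gave adjusted p = 6.1e-04, 0.0091 and 0.0204. Contractile and adhesion genes under TGF-beta, YAP and SRF gave 3 up and 6 down of 28 (3 and 7 adjusted over the list alone, median -0.17, adjusted p = 0.0412). Amotl2 fell by 2.10 and Ankrd1 fell by 1.74. That call was lost at adjusted p = 0.558 with an estimated correlation, and it was also lost with extreme local backgrounds replaced.

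At 8 h in KO1 the largest rise was that of Efr3b, which anchors a lipid kinase at the plasma membrane, by 6.92 ± 0.52 (adjusted p = 1.9e-13, probe A_55_P1956418). Ptgs2, the inducible cyclooxygenase, followed with a rise of 6.31 ± 0.70 (adjusted p = 1.7e-09). Their treated arrays varied far more than the control arrays (SD 2.19 against 0.14 for Efr3b, 2.01 against 0.18 for Ptgs2). The SE and p rest on a spread shared by all groups and do not measure this. Zfand2a rose by 5.82, Hsph1 by 5.72, Hmox1 by 5.71, Dnajb1 by 5.65, the stress cytokine Gdf15 by 5.57, Srxn1 by 5.49 and Phlda1 by 5.48. Tex19.1, a gene of germ cells, rose by 5.73 ± 0.51 (adjusted p = 1.1e-11). Its Cy5 signal was not well above background on the control arrays, so the size of this rise is uncertain. Aqp5 fell by 3.58 (its second probe gave -1.43), the calcium-binding S100a4 fell by 3.20, the tendon transcription factor Scx fell by 3.13 and Phlda3, a p53 target that restrains AKT, fell by 2.69 ± 0.10 (adjusted p = 1.1e-20, probe A_51_P329928). Further falls were those of Commd5 (-3.05), Foxa1 (-3.04), Tmem140 (-2.73), Zfp41 (-2.73), Mterf2 (-2.72) and Ajuba (-2.69). Each held in 4 of 4 treated arrays, as the rule for the genes named requires. In all 8619 genes passed (4040 up and 4579 down), which is 55.2% of the genes tested, 2261 of them by at least 2-fold, and 2177 passed with scale normalization between arrays.

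Protein quality control genes rose broadly in KO1 at 8 h: 30 of 31 heat shock genes (30 adjusted over the list alone, median 2.86, adjusted p = 3.7e-27, 0.0070 with an estimated correlation). An example was the small chaperone Hspb8 (3.06). Of 38 proteasome subunits 31 rose and none fell (31 adjusted over the list alone, median 0.61, adjusted p = 4.6e-08, 0.544 with an estimated correlation). Among them were the ubiquitin receptor Adrm1 (1.76 ± 0.13), Psmc2 (1.60) and Psmd12 (1.55). Genes of the unfolded protein response of the endoplasmic reticulum rose in 19 of 25 cases and fell in 2 (20 and 2 adjusted over the list alone, median 0.58, adjusted p = 3.5e-06, 0.358 with an estimated correlation). The chaperone Hspa5 rose by 3.64 ± 0.29. Of 35 autophagy and lysosome genes 20 rose and 2 fell (20 and 2 adjusted over the list alone, median 0.43, adjusted p = 1.8e-05, 0.391 with an estimated correlation). The cargo receptor Sqstm1 rose by 3.62. ATF4 targets rose in 32 of 35 cases (32 adjusted over the list alone, median 1.75, adjusted p = 1.3e-16, 0.0353 with an estimated correlation). They included the phosphatase subunit Ppp1r15a (4.04 ± 0.17) and the cysteine synthesis enzyme Cth (3.80). NRF2 targets rose in 28 of 33 cases (28 adjusted over the list alone, median 1.98, adjusted p = 1.8e-14, 0.121 with an estimated correlation). Txnrd1 rose by 5.26 ± 0.24. Immediate early genes gave 20 up and 4 down of 30 (21 and 4 adjusted over the list alone, median 1.44, adjusted p = 1.8e-04, 0.558 with an estimated correlation). The AP-1 subunit Fosl1 rose by 4.44.

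Genes of proliferation and sterol synthesis fell in KO1 at 8 h. Of 34 cell cycle genes 27 fell and none rose (28 adjusted over the list alone, median -0.88, adjusted p = 1.1e-06, 0.543 with an estimated correlation). Among them were cyclin D1, Ccnd1 (-2.10), the mitotic kinase Plk1 (-2.07) and the ribonucleotide reductase Rrm1 (-1.80). Of 25 cholesterol synthesis genes 16 fell and 1 rose (17 and 3 adjusted over the list alone, median -0.68, adjusted p = 0.0036, 0.688 with an estimated correlation). Hmgcs1 fell by 2.67 and Mvk fell by 2.10. Interferon response genes fell in 17 of 31 cases and rose in 3 (17 and 3 adjusted over the list alone, median -0.71, adjusted p = 0.0184, 0.714 with an estimated correlation). Parp14 fell by 1.94 and Stat2 fell by 1.23, but the chemokine Cxcl10 rose by 2.99. NF-kappaB genes gave 14 up and 3 down of 28 (14 and 3 adjusted over the list alone, median 0.16, adjusted p = 0.0282, 0.621 with an estimated correlation). The cytokine Il6 rose by 3.06 and Csf1 by 3.12. The p53 targets went both ways, with 8 up and 11 down of 27 (8 and 11 adjusted over the list alone, median -0.02, adjusted p = 0.641), as the cyclin G gene Ccng1 (-2.10) and Zmat3 (-1.65) fell and the death receptor Tnfrsf10b rose (2.00). Iron and heme genes gave 15 up and 9 down of 34 (15 and 9 adjusted over the list alone, adjusted p = 0.145). The heme exporter Flvcr1 rose by 1.99 and the iron transporter Slc11a2 by 1.94. Glycolysis and hypoxia genes gave 8 up and 7 down of 30 (8 and 7 adjusted over the list alone, adjusted p = 0.602). The glucose transporter Slc2a1 rose by 3.44 and Vegfa by 2.06.

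In KO3 at 4 h, Cxcl1 rose by 4.76 ± 0.67 (adjusted p = 2.2e-05, probe A_51_P363187) and the HSP70 chaperone Hspa1a by 4.56 ± 0.44 (adjusted p = 9.6e-09, probe A_55_P2068459). The NRF2 target Osgin1 rose by 4.30 and Gdf15 by 3.89. Gas1, a growth arrest gene, fell by 1.94 ± 0.23 (its other probes gave -0.64 and -0.52), and the AP-1 subunit Fosl2 fell by 1.96 with 1 probe while the other gave -0.07. The BMP ligand Gdf6 (-1.93, adjusted p = 0.0426) and the interferon-induced Ifit3 (-1.61) and Rtp4 (-1.60, adjusted p = 0.0448) fell too. Each held in 3 of 3 treated arrays, as the rule for the genes named requires. The calls of Gdf6 and Rtp4 were lost in 10 of 23 and 10 of 24 refits. Heat shock genes rose in 20 of 31 cases (24 adjusted over the list alone, median 0.92, adjusted p = 3.8e-47). NRF2 targets rose in 16 of 33 (21 adjusted over the list alone, median 1.06, adjusted p = 4.4e-36) and ATF4 targets in 13 of 35 (25 adjusted over the list alone, median 0.70, adjusted p = 8.0e-31). NF-kappaB genes rose in 6 of 28 cases (11 up and 1 down adjusted over the list alone, median 0.42), and p53 targets gave 8 up and 1 down of 27 (13 and 2 adjusted over the list alone, median 0.34). These 5 lists kept their call with an estimated correlation, at adjusted p = 6.1e-04, 0.0040, 0.0037, 0.0070 and 0.0287. In all 256 genes passed (187 up and 69 down), 122 of them by at least 2-fold, and 1706 had an unadjusted p under 0.05. With median centring or with scale normalization between arrays fewer genes passed, and falls outnumbered rises. With extreme local backgrounds replaced the count was 989, which held all 256, and it was 63 and 82 without either of the control arrays and 453 without KO3_4h replicate b, whose fitted background was among the widened ones.

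In KO3 at 8 h the largest rise was that of Ptgs2, by 5.70 ± 0.90 (adjusted p = 6.1e-06, probe A_51_P254855). Gdf15 rose by 5.56, Osgin1 by 5.35, Hspa1a by 5.14, Cxcl1 by 5.07, Hmox1 by 4.99, Srxn1 by 4.70, Phlda1 by 4.60 and Gsta1 by 4.46. Gas1 fell by 3.09 ± 0.23 (adjusted p = 3.8e-12, probe A_51_P157083, the other probes at -1.18 and -0.70) and Rtp4 fell by 2.92. Other falls were Ifit1 (-2.85), the pro-apoptotic Bmf (-2.82), Fosl2 (-2.67, other probe -0.46), Pxylp1 (-2.64, other probe -0.71), the chemokine scavenger Ackr3 (-2.55), Cdon (-2.49, other probe -0.55), Cavin2 (-2.47) and Aqp5 (-2.46, other probe -0.57). Each held in every treated array with a value, as the rule for the genes named requires. In all 5457 genes passed (2419 up and 3038 down), which is 34.9% of the genes tested, 1274 of them by at least 2-fold. The count was 3549 and 3462 without either of the control arrays and 529 with scale normalization between arrays.

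Heat shock genes rose in KO3 at 8 h in 29 of 31 cases (29 adjusted over the list alone, median 1.89, adjusted p = 1.1e-29). Members that passed included Hspb8 (2.72) and the constitutive HSP70 Hspa8 (2.50). ATF4 targets rose in 32 of 35 (32 adjusted over the list alone, median 1.33, adjusted p = 1.0e-20). Ppp1r15a, for example, rose by 3.16. NRF2 targets gave 29 up and 1 down of 33 (29 and 1 adjusted over the list alone, median 1.90, adjusted p = 3.6e-20), such as Txnrd1 (4.19) and Gclc (4.14). These 3 held with an estimated correlation, at adjusted p = 0.0041, 0.0168 and 0.0353. The p53 targets gave 15 up and 5 down of 27 (15 and 6 adjusted over the list alone, median 0.88, adjusted p = 4.1e-04, 0.251 with an estimated correlation). The pro-apoptotic Pmaip1 rose by 2.61, Tnfrsf10b by 2.18 and Mdm2 by 1.75. Interferon genes fell in 23 of 31 cases and rose in 2 (26 and 2 adjusted over the list alone, median -1.12, adjusted p = 6.1e-08, 0.416 with an estimated correlation). Collagen and matrix genes fell in 18 of 33 cases and rose in 1 (20 and 1 adjusted over the list alone, median -0.49, adjusted p = 1.2e-04, 0.305 with an estimated correlation). Col3a1 fell by 1.57 and Sparc fell by 1.22. Cell cycle genes fell in 19 of 34 cases (20 down and 1 up adjusted over the list alone, median -0.63, adjusted p = 2.1e-04, 0.639 with an estimated correlation). Proteasome subunits rose in 13 of 38 (13 adjusted over the list alone, median 0.32, adjusted p = 1.8e-05, 0.638 with an estimated correlation).

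**Figure D2:**
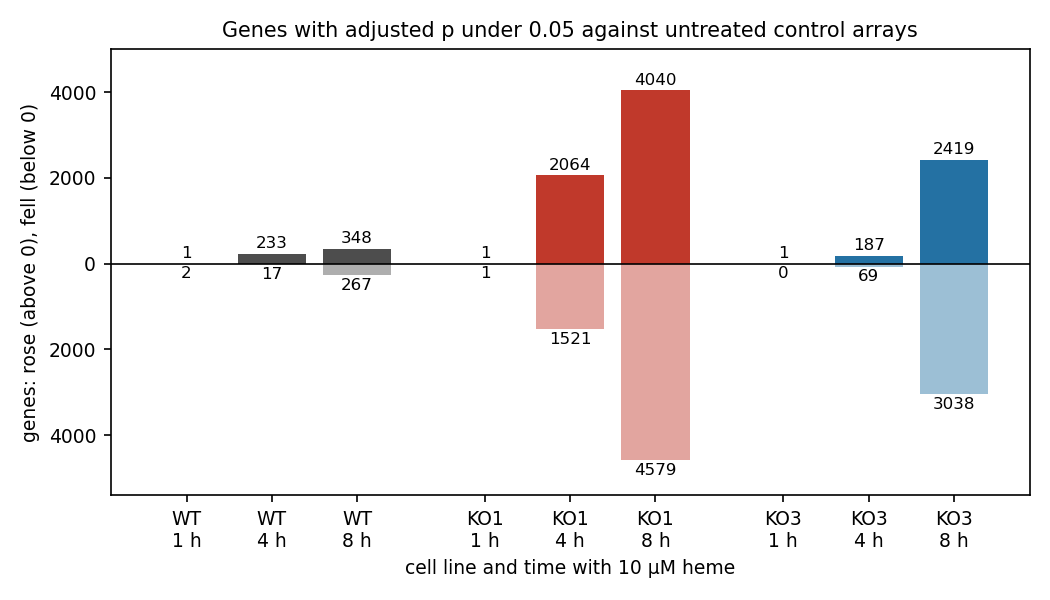
Number of genes past adjusted p 0.05 in each line by hours of heme, with bars for genes that rose and for genes that fell. Counts at 8 h were 615 in WT, 8619 in KO1 and 5457 in KO3, and the split between rises and falls moved under other scalings (in WT at 8 h from 56.6% up to 88.3% with median centring).

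The KO minus WT contrast compares the heme response of the knockout lines with that of the WT line. Its SE and p rest on the spread between arrays of the same line. They do not measure how lines vary, so they do not test the genotype apart from the lines. At 4 h the chaperone genes Hspa1a (3.73 ± 0.44, adjusted p = 1.0e-06) and Dnajb1 (3.67 ± 0.44, adjusted p = 1.8e-06) rose more in the knockout lines than in WT. The same was found for Phlda1 (3.14) and Osgin1 (2.96). Ccl2, which rose in WT, was lower by the same contrast (-3.09 ± 0.29, adjusted p = 7.7e-09), although scale normalization between arrays turned its sign (1.70). Also lower were Vcam1 (-2.21), Ifit1 (-2.53), Rtp4 (-2.43) and the interferon-induced GTPase Ifi47 (-2.13, adjusted p = 0.0275, lost in 10 of 39 refits). Against WT, Vcam1, Ifit1 and Ifi47 passed in KO1 but not in KO3 (adjusted p = 0.563, 0.159 and 0.458), and neither did Phlda1 in KO3 (adjusted p = 0.242). Alas1 fell in WT (-1.82) and KO3 (-0.83, adjusted p = 0.0408) but rose in KO1 (0.78, adjusted p = 7.2e-04), with a KO minus WT difference of 1.80 (adjusted p = 1.8e-06). Heat shock genes differed in 23 of 31 cases, all higher (27 adjusted over the list alone, median 1.24, adjusted p = 3.9e-62, 1.6e-04 with an estimated correlation). ATF4 targets were higher in 4 of 35 cases (16 higher and 1 lower adjusted over the list alone, median 0.55, adjusted p = 2.4e-15, 0.0490 with an estimated correlation). Ppp1r15a differed by 1.86. Interferon genes were lower in 5 of 31 cases (18 adjusted over the list alone, median -0.57, adjusted p = 3.3e-12), a call lost at adjusted p = 0.228 with an estimated correlation. NRF2 targets were higher in 4 of 33 cases (5 adjusted over the list alone, median 0.30, adjusted p = 1.1e-06), a call lost at adjusted p = 0.454 with an estimated correlation. At 4 h 277 genes passed (136 higher and 141 lower, or 49.1% higher, against 18.0% with median centring), 105 of them by at least 2-fold, with 2142 at unadjusted p under 0.05, and 994 passed with extreme local backgrounds replaced, 276 of them shared. Taken singly against WT, 880 genes differed in KO1 and 28 in KO3 at 4 h, 19 of them in both. KO3 had fewer arrays and the 277 genes were not split by line, so these counts do not show how much each line adds. KO1_4h replicate b and KO3_4h replicate b had flattened ratios, and KO3_4h replicate a had 4023 outlier spots (median 233 over all arrays). These counts of single lines and of shared genes were not redone with extreme local backgrounds replaced. Both contrasts share the WT arrays. With the WT arrays parted between them, which leaves fewer for each, 2 to 7 genes were shared in 18 splits (median 4), against 0.04 to 0.10 if independent.

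At 8 h the KO minus WT difference was largest for Ptgs2 (5.33 ± 0.90, adjusted p = 1.8e-05), Hspa1a (4.76 ± 0.44, adjusted p = 1.9e-10) and Gdf15 (4.70). Zfand2a (4.27), Phlda1 (4.26), Dnajb1 (4.23), Hsph1 (4.11), Osgin1 (4.03) and Srxn1 (3.98) followed. Rtp4, which helps receptors reach the membrane and is induced by interferon, was lower (-3.48 ± 0.43, adjusted p = 9.1e-08, probe A_51_P304170), as were the interferon-induced GTPases Tgtp2 (-3.20, other probe -0.05) and Ifi47 (-3.15). Ccl2 was lower by the same contrast (-3.10 ± 0.29, adjusted p = 2.2e-10), as were the vessel growth factor Angpt1 (-2.99), Ifit1 (-2.88), the activin subunit Inhbb (-2.69), Kank3 (-2.58), Wdr6 (-2.44) and Serpinb6b (-2.42). These 19 genes had the same sign in both knockout lines, which the rule for the genes named requires, so it is not a separate result. Cyp1a1, which fell in WT, differed by 3.85 (adjusted p = 1.7e-05), and Alas1 by 1.73 (adjusted p = 1.4e-07), although Alas1 rose in KO1 (0.91) and fell in KO3 (-0.81, adjusted p = 0.0037). At 8 h 5725 genes passed (2379 higher and 3346 lower), 36.7% of the genes tested and 1346 of them by at least 2-fold. With scale normalization between arrays 430 passed, and with median centring the share higher was 26.1% (41.6% before). Against WT, 6399 genes differed in KO1 and 3034 in KO3, of which 2327 differed with the same sign (895 higher and 1432 lower) and 24 with opposite signs. KO1_8h replicate a and KO3_8h replicate c had flattened ratios, and these counts were not redone with extreme local backgrounds replaced. Both contrasts share the WT arrays, which alone makes overlap: with the WT arrays parted between them, 1237 to 1534 genes were shared in 18 splits (median 1382), against 284 to 382 if independent.

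Of the lists at 8 h, heat shock genes were higher in the knockout lines in 28 of 31 cases (28 adjusted over the list alone, median 2.31, adjusted p = 8.3e-34, 0.0028 with an estimated correlation). ATF4 targets were higher in 30 of 35 (32 adjusted over the list alone, median 1.30, adjusted p = 1.1e-19, 0.0204 with an estimated correlation). Among them were Ppp1r15a (3.55 ± 0.21), Cth (3.20) and the serine synthesis enzyme Psph (2.58). NRF2 targets gave 20 higher and 4 lower of 33 (21 and 4 adjusted over the list alone, median 0.78, adjusted p = 8.6e-08, 0.385 with an estimated correlation). Txnrd1 differed by 3.87 ± 0.32 and Prdx1 by 2.04. Interferon genes were lower in 25 of 31 cases and higher in 1 (27 and 1 adjusted over the list alone, median -1.27, adjusted p = 3.6e-09, 0.349 with an estimated correlation). Stat2 differed by -1.53 ± 0.17 (adjusted p = 9.9e-09) and Parp14 by -2.30. Cholesterol synthesis genes were lower in 14 of 25 (16 adjusted over the list alone, median -0.79, adjusted p = 0.0019, 0.688 with an estimated correlation). Cell cycle genes were lower in 18 of 34 (18 lower and 1 higher adjusted over the list alone, median -0.55, adjusted p = 0.0040, 0.691 with an estimated correlation). Proteasome subunits were higher in 9 of 38 (9 adjusted over the list alone, median 0.29, adjusted p = 6.3e-04, 0.688 with an estimated correlation). Adrm1 differed by 1.19. The unfolded protein response gave 12 higher and 1 lower of 25 (12 and 2 adjusted over the list alone, median 0.25, adjusted p = 9.97e-04, 0.576 with an estimated correlation). Autophagy genes gave 13 higher and 2 lower of 35 (13 and 3 adjusted over the list alone, median 0.17, adjusted p = 0.0067, 0.638 with an estimated correlation). NF-kappaB genes went both ways, with 6 higher and 9 lower of 28 (7 and 9 adjusted over the list alone, adjusted p = 0.880).

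**Figure D3:**
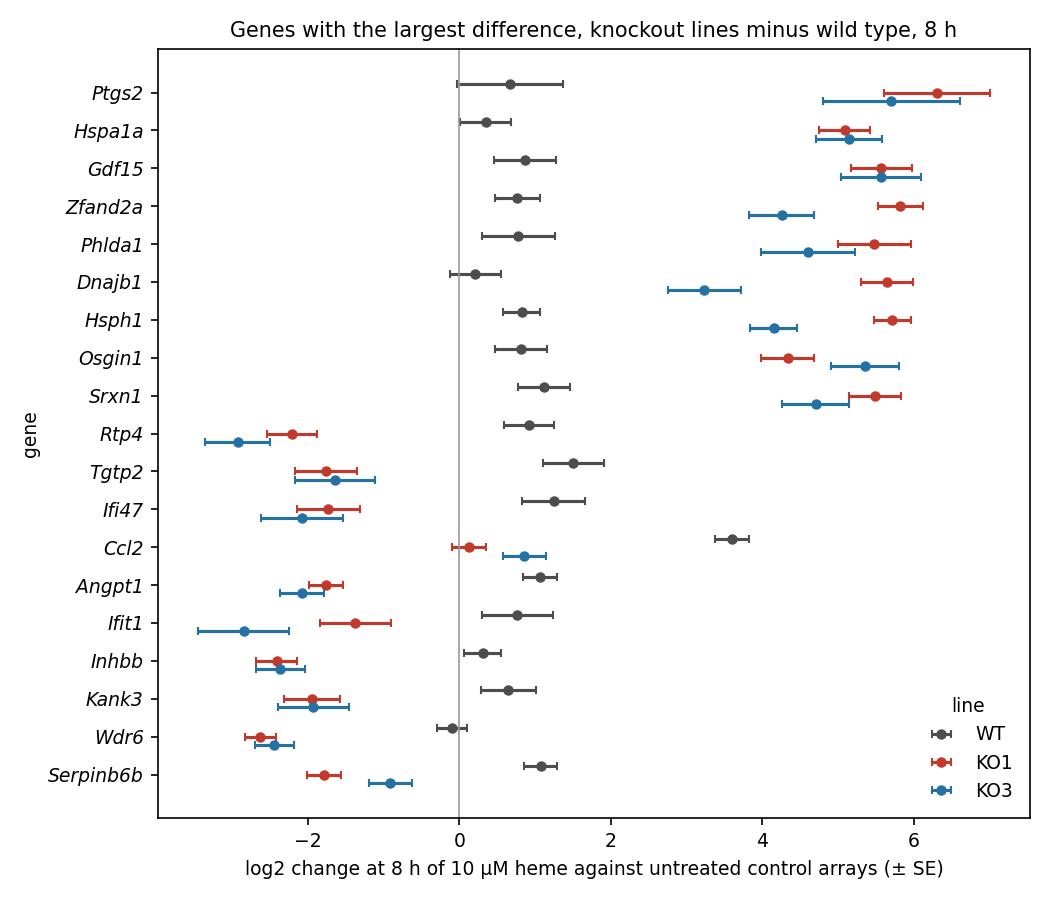
Log2 change at 8 h of heme in each line (points, with bars for ± SE) for 19 genes among those with the largest KO minus WT differences in either direction. Ptgs2 had a log2 change of 6.31 in KO1 and 5.70 in KO3 against 0.67 in WT, and Ccl2 of 3.60 in WT against 0.13 in KO1 and 0.86 in KO3.

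**Figure D4:**
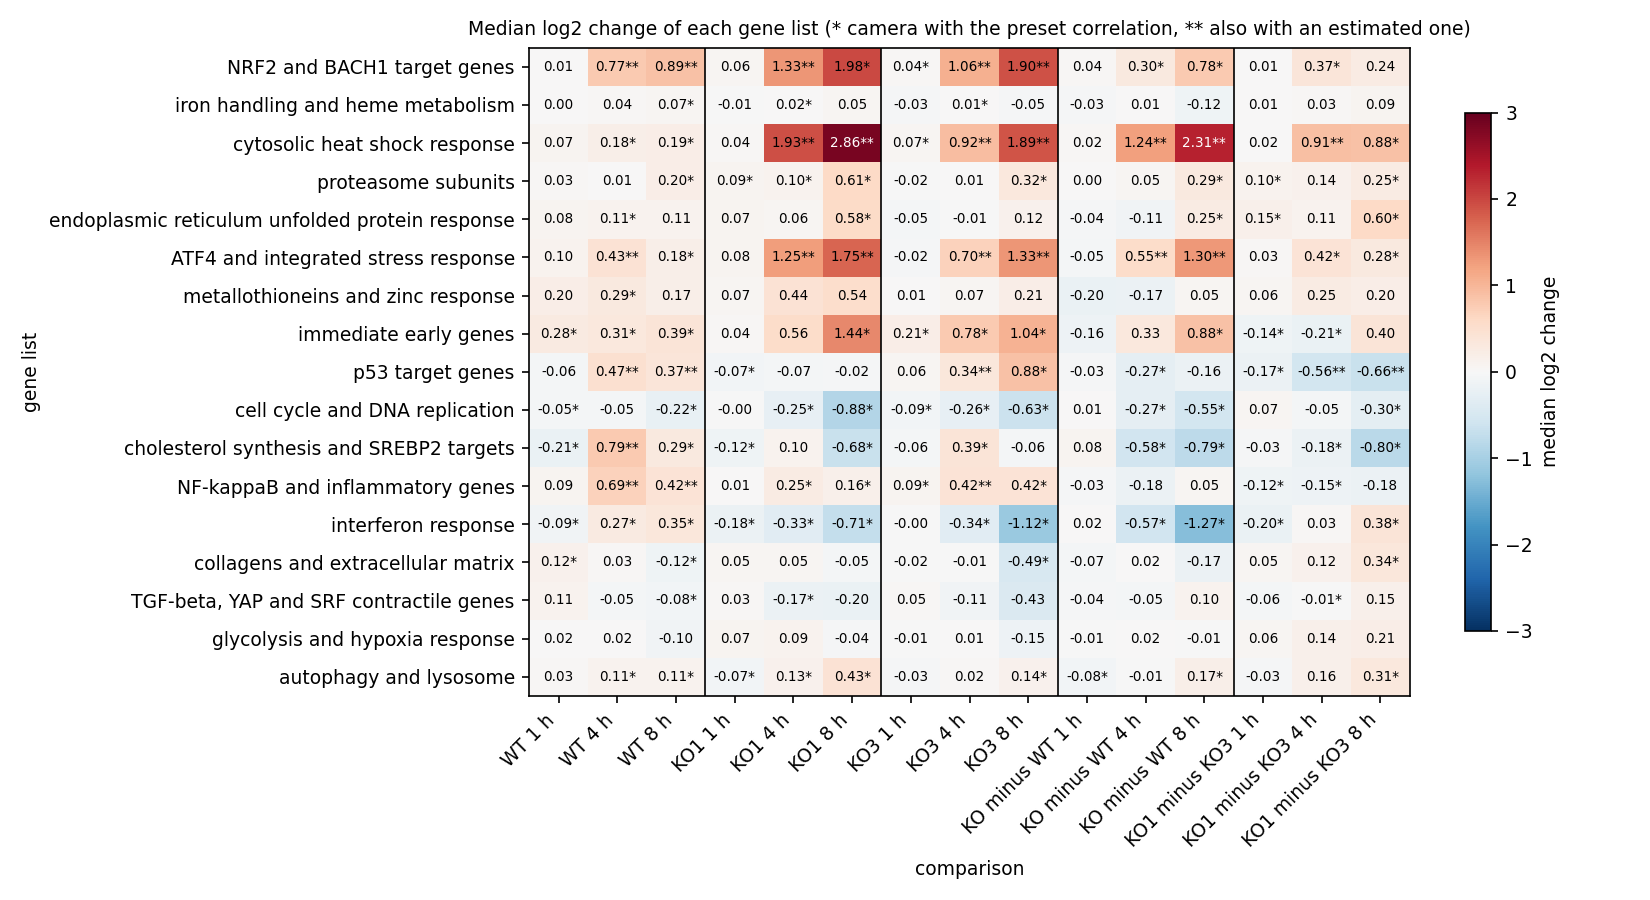
Median log2 change of the members of each of the 17 pathway lists (colour) in each of the 15 contrasts, with 1 star where the list test passed and 2 stars where it also passed with an estimated correlation. Heat shock genes had a median of 2.86 in KO1 and 0.19 in WT at 8 h.

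The 2 knockout lines came from different embryos, so KO1 minus KO3 shows how far lines of the same genotype differed. At 4 h heat shock genes rose more in KO1 than in KO3 in 12 of 31 cases (24 higher and 1 lower adjusted over the list alone, median 0.91, adjusted p = 4.1e-26, 0.0075 with an estimated correlation). The HSP40 chaperone Dnaja1 differed by 1.59 and Cacybp by 1.32. The p53 targets were lower in KO1 in 6 of 27 cases (13 adjusted over the list alone, median -0.56, adjusted p = 1.6e-16, 0.0014 with an estimated correlation). Phlda3 differed by -1.31 and the pro-apoptotic Bbc3 by -1.91. At 8 h p53 targets were lower in 11 of 27 (14 lower and 1 higher adjusted over the list alone, median -0.66, adjusted p = 1.0e-09, 0.0127 with an estimated correlation). Phlda3 differed by -1.69 ± 0.17 (adjusted p = 2.0e-08), Aen by -2.11 and Bbc3 by -1.96. Heat shock genes were higher in 16 of 31 and lower in 1 (21 and 1 adjusted over the list alone, median 0.88, adjusted p = 1.3e-11, 0.132 with an estimated correlation). The collagen chaperone Serpinh1, for example, differed by 1.84. The unfolded protein response was higher in 7 of 25 (14 adjusted over the list alone, median 0.60, adjusted p = 1.1e-08, 0.198 with an estimated correlation). Hspa5 differed by 2.24 (adjusted p = 0.0015). Cholesterol synthesis genes were lower in 8 of 25 (13 adjusted over the list alone, median -0.80, adjusted p = 2.5e-07, 0.507 with an estimated correlation). Examples were Hmgcs1 (-2.33) and Sqle (-1.80). Collagen genes were higher in 6 of 33 (9 adjusted over the list alone, median 0.34, adjusted p = 1.1e-04, 0.307 with an estimated correlation). Col3a1 differed by 1.69. NRF2 targets gave 3 higher and 1 lower of 33 (3 and 1 adjusted over the list alone, adjusted p = 0.487). At 4 h 117 genes passed (75 higher and 42 lower, 66 of them by at least 2-fold, 1427 at unadjusted p under 0.05), and at 8 h 1704 (839 higher and 865 lower, 523 by at least 2-fold). With extreme local backgrounds replaced these counts were 359 and 3150, of which 115 and 1698 were shared.

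Hmox1 was the single gene that rose in all 3 lines at 1 h, and at 8 h 135 genes rose and 104 fell in all 3 (51 and 2 at 4 h). KO1 and KO3 shared 1909 rises and 2377 falls at 8 h, against 626 and 891 if the calls were independent across genes, and 116 genes had opposite signs. WT and KO1 shared 165 rises and 138 falls at 8 h with 67 of opposite sign, against 90.0 rises and 78.3 falls if independent. WT and KO3 shared 164 and 138 with 33 of opposite sign, against 53.9 and 51.9 if independent. Of the genes past the threshold at 4 h, 125 of 250 in WT, 3226 of 3585 in KO1 and 251 of 256 in KO3 also passed with the same sign at 8 h. Lists called independently would share 5.19 rises and 0.291 falls in WT, 534 and 446 in KO1 and 29.0 and 13.4 in KO3. Both times share the control arrays of their line, which alone makes signs agree (mean correlation of the changes in 20 simulations of unchanged groups 0.503 in WT, 0.502 in KO1 and 0.594 in KO3). With the control arrays parted between the 2 times, 32 to 37 genes were shared in WT (0.743 to 0.963 if independent) and 1828 to 2059 in KO1 (525 to 630 if independent), in 6 splits each. KO3 has 2 control arrays, so part of its excess may come from them. Within each slide that held treated and control arrays of a line, at least 99.1% of the genes called in that line kept their sign, which the choice of genes by these same arrays largely sets. No slide allows KO minus WT, since no slide holds treated and control arrays of each line. Of the genes called at 8 h with several kept probes, a probe of opposite sign was found for 12 of 197 in WT, 445 of 2458 in KO1 and 221 of 1614 in KO3.

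Marker genes of other cell types were examined for changes with heme. Other cells present in both channels cancel in the ratio, so these values do not show whether such cells were there. In KO1 at 8 h, the endothelial list gave 5 up and 1 down of 10 (5 and 1 adjusted over the list alone, median 0.22, adjusted p = 0.182). Leukocyte genes gave 1 up and 2 down of 10 (0 and 2 adjusted over the list alone, adjusted p = 0.613), and epithelial genes 4 up and 3 down of 12 (4 and 3 adjusted over the list alone, adjusted p = 0.705). Muscle genes gave 3 up of 11 (3 adjusted over the list alone, adjusted p = 0.487), and neural genes 2 up and 1 down of 14 (2 and 1 adjusted over the list alone, adjusted p = 0.609). Of the 6 lists in 15 contrasts, the single call was that of erythroid genes in KO1 minus KO3 at 1 h (median -0.17, adjusted p = 0.0412). None of its 6 members passed (0 adjusted over the list alone), and the call was lost at adjusted p = 0.190 with an estimated correlation.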

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

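Among the tests below, those of a higher untreated level of interferon genes in KO3 and of p53 targets in KO1, those with extreme local backgrounds replaced and that of the size of changes with 1 array left out were chosen after the result was seen, and the tests without the slide 9 control arrays use an alternative added after the data were seen.

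The difference between the lines was itself tested. KO minus WT had 277 genes at 4 h and 5725 at 8 h past the threshold, and KO1 minus KO3 had 117 and 1704. With extreme local backgrounds replaced, KO minus WT had 994 at 4 h and KO1 minus KO3 359 and 3150. With 1 array left out in turn, KO1 minus KO3 had 31 to 152 and 740 to 3049. With the list test, heat shock genes were higher in the knockout lines than in WT at 4 h (median 1.24) and 8 h (2.31), and in KO1 than in KO3 at 4 h (0.91). ATF4 targets were higher in the knockout lines at 4 h (0.55) and 8 h (1.30). The p53 targets were lower in KO1 than in KO3 at 4 h (-0.56) and 8 h (-0.66). With 1 WT line, the KO minus WT differences belong to the lines as well as to the genotype.

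More genes passed in KO1 (8619) than in KO3 (5457) at 8 h. Without either KO3 control array KO3 had 3549 and 3462, without the flattened KO3_8h replicate c it had 6303, and with scale normalization the counts were 2177 and 529. A smaller number of arrays in KO3 was argued against as the whole cause: with 3 treated and 2 control arrays, KO1 gave 6482 to 8447 genes in 24 draws (median 7083.5). With extreme local backgrounds replaced, which undoes the flattening, such draws gave 7860 to 8774 against 6806 in KO3. Wide ratios on the control arrays of slide 9 were argued against too, as KO1 without them gave 7611. A larger change per gene in KO1 remains open: over 4402 genes past the threshold in both lines, the size was larger in KO1 for 2871, by a median of 0.12. This median was 0.04 to 0.19 with 1 array left out in turn and 0.15 with extreme local backgrounds replaced. Differences between the embryos or cultures behind the lines stay open and were not tested.

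The p53 targets changed less upward in KO1 than in KO3 at 8 h, by a list median of -0.66. The slide 9 control arrays do not account for it, since the median was -0.61 without them, and neither does the normalization, since the median nearest to 0 among the other normalizations was -0.71 (median centring). A lower untreated level in KO1 is argued against, because untreated KO1 cells had a list median 0.98 above that of KO3, with 4 of 27 members lower in KO1. That same value, 0.98, is what a higher untreated level in KO1 needs, so a starting point already high in KO1 or low in KO3 may contribute (list median against WT 0.25 in KO1 and -0.95 in KO3). It was seen before that test was chosen, and untreated levels were compared across arrays without a test.

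Interferon response genes were lower in the knockout lines than in WT at 8 h, by a list median of -1.27, a call lost with an estimated correlation (adjusted p = 0.349). The call of this list within each line at 8 h was lost with an estimated correlation as well, and most members did not pass in WT. By the medians alone, the list rose in WT (0.35) and fell in KO1 (-0.71) and KO3 (-1.12), so both sides add to the difference. Signals near background do not account for it, as the 20 members well above background on all arrays had a median of -1.36. With slide as a block the median was -1.35, which argues against an offset shared by all arrays of a slide. No slide held treated arrays of different lines, so slides that differ in the size of heme changes cannot be told apart from the lines. A higher untreated level in both knockout lines is argued against, since in KO1 the list lay at -0.23 against WT (quartiles -0.67 and 0.06). Untreated levels were compared without a test across arrays, and the lines lay mostly on different slides. A higher untreated level in KO3 alone remains open for KO3, where the list lay at 0.84 above WT, and could add to the fall in that line but not to that in KO1. Loss of Hmox1 is a further open explanation, which cannot be separated from other differences between the lines.

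Other splits of the same arrays were counted for WT and KO1 against their control arrays and for KO minus WT. KO3 against its 2 control arrays and KO1 minus KO3 were not split. For WT the real split gave 3, 250 and 615 genes at 1, 4 and 8 h, and the highest of the other splits 0, 0 and 4. For KO1 it gave 2, 3585 and 8619, against 0, 41 and 5915. In each case only 1 of 35 splits, the real one, gave as many, which is the smallest share that 35 splits allow. Splits that mix treated with control arrays also widen the residual spread, which lowers their counts. Several comparisons were counted without adjustment, so chance is made less likely but is not excluded. The split with 5915 genes moves KO1_8h replicate a, an array with a widened fitted background and flattened ratios, to the side of 3 control arrays, so it still parts most treated from control arrays. For KO minus WT, 100 splits of the line labels were drawn, the real one included. Only the real one gave as many genes at 4 h (277, highest other 15) and at 8 h (5725, highest other 4892). Chance in how arrays fall to the lines is thus less likely there, although splits that mix lines widen the residual spread too. The arrays repeat 3 lines, so these splits do not test chance differences between lines of a genotype. At 1 h limma gave 0 genes (270 at unadjusted p under 0.05), so 100 of 100 splits gave as many by construction (highest other 7). That count cannot decide on chance.

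Single arrays stood far from the others of their group in 13 of 176 groups of values tested, where chance gives about 1 in 20. The median signals of WT_0h replicate d were 543 in Cy3 (others 89 to 128) and 1306 in Cy5 (others 142.5 to 200.5). The SD of the log2 ratios was 0.314 on WT_4h replicate b (others 0.253 to 0.260) and 0.422 on WT_8h replicate b (others 0.283 to 0.307). On WT_8h replicate b the median log2 ratio was also high for immediate early genes (0.80, others 0.08 to 0.13) and cholesterol synthesis genes (0.85, others 0.00 to 0.15). On WT_4h replicate d Hmox1 had a log2 ratio of 4.29 with probe A_51_P263965 (others 3.75 to 3.80), and glycolysis and hypoxia genes a median of 0.0650 (others -0.06 to -0.04). WT_1h replicate c had a median of -0.16 for ATF4 targets (others 0.08 to 0.12). KO1_1h replicate d had a median of -0.0942 for iron and heme genes (others 0.01 to 0.02). The median of p53 targets was -0.0517 on KO1_0h replicate b (others -0.02 and -0.01) and -0.46 on KO1_8h replicate b (others -0.04 to -0.01). Cell cycle genes had a median of -0.60 on KO1_8h replicate a, the array with flattened ratios (others -0.98 to -0.95).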

How the results depend on the processing

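The alternatives with 5 arrays that stood apart left out, with the slide 9 control arrays left out and with extreme local backgrounds replaced were chosen after seeing the data. Unless a cause is given, the cause was not tested. A count is given below where it moved by more than 1.5 times. The counts were 3, 250 and 615 in WT at 1, 4 and 8 h, 2, 3585 and 8619 in KO1, 1, 256 and 5457 in KO3, 0, 277 and 5725 for KO minus WT, and 0, 117 and 1704 for KO1 minus KO3. No count moved by that much without a filter on dim probes, with a filter on both channels of all arrays, or with an intensity trend and robust prior.

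Median centring gave 10 and 171 genes in WT at 1 and 8 h, 1 and 1338 in KO1 at 1 and 4 h, 0 and 66 in KO3 at 1 and 4 h, and 7 and 461 for KO1 minus KO3 at 4 and 8 h (limma; for KO3 at 1 h 134 at unadjusted p under 0.05). It moved the median log2 change of all genes in WT to 0.28, 0.23 and 0.14 at 1, 4 and 8 h, in KO3 at 4 h to -0.18, for KO minus WT to -0.33, -0.27 and -0.22 and for KO1 minus KO3 at 1 and 4 h to 0.13 and 0.26, against -0.03 to 0.04 with loess, and changes of genes and lists under it are relative to those shifts. The share of called genes that went up moved from 56.6% to 88.3% in WT at 8 h, from 57.6% to 74.5% in KO1 at 4 h, from 46.9% to 36.4% in KO1 at 8 h, from 73.0% to 45.5% in KO3 at 4 h, from 44.3% to 34.0% in KO3 at 8 h, from 49.1% to 18.0% and from 41.6% to 26.1% for KO minus WT at 4 and 8 h, and from 64.1% to 85.7% for KO1 minus KO3 at 4 h.

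Scale normalization between arrays gave 0, 7 and 41 genes in WT, 0, 487 and 2177 in KO1, 0, 62 and 529 in KO3, 21 and 430 for KO minus WT at 4 and 8 h, and 10 and 40 for KO1 minus KO3. By construction it inflates the arrays flattened by the background fit, whose spread was as low as 0.0803 of the typical array. It reversed Ccl2 for KO minus WT at 4 h (1.70), NRF2 targets for KO1 minus KO3 at 4 h (-1.83, 0.37 before) and ATF4 targets for KO1 minus KO3 at 4 h (-0.84, 0.42 before). Shares up were 57.1% in WT at 4 h (93.2% before), 41.5% in WT at 8 h, 40.3% and 55.0% in KO3 at 4 and 8 h, and 33.3% and 40% for KO minus WT and KO1 minus KO3 at 4 h.

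Extreme local backgrounds replaced gave 989 in KO3 at 4 h, 994 for KO minus WT at 4 h, and 359 and 3150 for KO1 minus KO3 at 4 and 8 h. Agilent processed signals gave 4 and 5669 in KO1 at 1 and 4 h, 968 in KO3 at 4 h, 1083 for KO minus WT at 4 h, and 356 and 3248 for KO1 minus KO3. No background subtraction gave 991, 1023, 405 and 3257 for KO3 at 4 h, KO minus WT at 4 h, and KO1 minus KO3 at 4 and 8 h, and values of the series table gave 1016, 1065, 336 and 3140. These 4 alternatives do not use the fitted background that widened on 6 arrays. The series table rests on the same Agilent processed signals, so it is not a separate measurement.

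Array quality weights gave 10, 1325 and 1378 in WT, 7 in KO1 at 1 h, 15 and 1674 in KO3 at 1 and 4 h, 1920 for KO minus WT at 4 h, and 826 and 3776 for KO1 minus KO3. Treated arrays tested against 0 without control arrays, which leaves dye effects in the change, gave 1629, 2691 and 3980 in WT, 1198 and 6642 in KO1 at 1 and 4 h, 308, 2698 and 8598 in KO3, 2 and 1775 for KO minus WT at 1 and 4 h, and 936 and 4620 for KO1 minus KO3. The mean of a gene's kept probes gave 0 in KO1 and 0 in KO3 at 1 h and reversed Hmox1 for KO minus WT at 4 h (-1.44) and 8 h (-0.95), since it averages in the probe with a low signal in the knockout lines. A fit of the arrays of 1 line gave 2293 in KO1 at 4 h and 0 and 109 in KO3 at 1 and 4 h, and no such fit exists for contrasts between lines.

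The replicate letter as a block gave 10 and 1024 in WT at 1 and 8 h, 0 and 430 in KO3 at 1 and 4 h, and 497 for KO minus WT at 4 h. Slide as a fixed block gave 420 and 1303 in WT at 4 and 8 h, 15 in KO1 at 1 h, 0 and 633 in KO3, 828 for KO minus WT at 4 h, and 222 and 3617 for KO1 minus KO3. Slide as a random block (consensus correlation 0.261) gave 6, 440 and 1355 in WT, 559 in KO3 at 4 h, 664 for KO minus WT at 4 h, and 232 and 2748 for KO1 minus KO3. Scan day as a block gave 1159 in WT at 8 h, 0 and 405 in KO3, 493 for KO minus WT at 4 h and 177 for KO1 minus KO3 at 4 h.

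With 5 arrays that stood apart left out (WT_0h replicates b and d, KO1_0h replicates a and b, KO3_4h replicate a), counts were 1, 36 and 109 in WT, 1 and 2073 in KO1, 0 and 94 in KO3 at 1 and 4 h, 55 for KO minus WT at 4 h, and 54 and 1111 for KO1 minus KO3. Without the slide 9 control arrays they were 139 and 350 in WT at 4 and 8 h, 1 and 2119 in KO1, 0 in KO3 at 1 h, 142 for KO minus WT at 4 h and 60 for KO1 minus KO3 at 4 h. Fewer arrays were left in both.

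Leaving out 1 array in turn gave 2 to 15, 100 to 214 and 299 to 734 genes in WT, 1 to 3, 2586 to 3839 and 7614 to 9123 in KO1, 0 to 6, 63 to 453 and 3462 to 6303 in KO3, 0 to 2, 176 to 363 and 5054 to 6542 for KO minus WT, and 0 to 2, 31 to 152 and 740 to 3049 for KO1 minus KO3. The count moved by over 1.5 times in 36 of 165 such fits. In WT these were at 1 h WT_1h replicates b (15) and c (5), at 4 h WT_4h b (152) and d (153) and WT_0h a (157), b (162) and d (100), and at 8 h WT_8h b (299) and WT_0h b (408), c (406) and d (379). In KO1 it was KO1_1h d (1) at 1 h. In KO3 they were at 1 h KO3_1h a (0) and b (0) and KO3_0h a (3) and b (6), at 4 h KO3_4h a (125), b (453) and c (123) and KO3_0h a (63) and b (82), and at 8 h KO3_0h a (3549) and b (3462). For KO minus WT they were KO3_0h a and b, with 1 and 2 at 1 h and 176 and 178 at 4 h. For KO1 minus KO3 they were KO3_0h a (2) and b (2) at 1 h, KO3_4h c (72), KO3_0h a (31) and b (40) and KO1_4h a (70) at 4 h, and KO3_0h a (797) and b (740) and KO1_8h a (3049) at 8 h. Without either KO3 control array the lone one left is assumed to vary like the other groups.

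Of 127 results for named genes past the threshold, 10 stayed past it with the same sign under each alternative that kept the gene and each array left out. The filter on both channels of all arrays kept 96 of 132 named gene results, and a dropped gene was not counted as lost. Among the 10, Gjb2, Nrip3, Cpm, Depp1, Efr3b and Tex19.1 had no value under that filter. Scale normalization took 116 below the threshold, the 5 arrays left out 21, median centring 11 and the slide 9 control arrays 10, and none of these 3 reversed any. Leaving out 1 array took 46 of 1407 below it. Of 345 list results, scale normalization weakened 59 and median centring 18, and median centring brought 63 past the threshold. Heat shock and ATF4 targets for KO minus WT at 4 and 8 h, interferon genes for KO minus WT at 8 h (-1.69 to -1.07) and p53 targets for KO1 minus KO3 at 4 h (-1.19 to -0.26) and 8 h (-1.30 to -0.39) kept their call under every alternative with the preset correlation. Signal over background limits 528 of the genes called in KO1 at 8 h, 154 in KO3 and 7 in WT, which were dim in at least 1 of the compared groups, so their fold changes depend on the offset. Of these, 82 in KO1 and 17 in KO3 were dim in both groups, so those calls themselves rest on Cy5 signals not well above background.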

Other observations

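No test in this part was chosen for a hypothesis, and its values are given without explanation.

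The channel with untreated cells gives the level of each list in the lines before heme, as means over arrays and without a test. Relative to WT, cholesterol synthesis genes had a list median of 1.36 in KO1 and -0.10 in KO3. Cell cycle genes lay at 0.83 in KO1 and 0.46 in KO3, and collagen and matrix genes at -0.94 in KO1 and -0.02 in KO3. The unfolded protein response lay at -0.40 in KO1 and 0.22 in KO3, and metallothioneins at 0.00 in KO1 and 0.56 in KO3. Over all genes the medians were 0.04 in KO1 and -0.01 in KO3. Between the knockout lines, interferon genes lay at -1.54 in KO1 relative to KO3 and cholesterol synthesis genes at 1.35.

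On 6 arrays (KO1_1h replicate a, KO1_4h replicate b, KO1_8h replicate a, KO3_1h replicate c, KO3_4h replicate b and KO3_8h replicate c) the fitted background was wide, with 21 to 77 spots of high local background each. With those backgrounds replaced, the SD of the log2 ratios of genes moved from 0.58 to 0.92 on KO1_8h replicate a and from 0.49 to 0.70 on KO3_8h replicate c.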
